A study of Mus musculus with 4 samples.

How the data were processed

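Genomic DNA of mouse ES cells was measured by reduced representation bisulfite sequencing in 4 libraries, 2 of WT and 2 of Naa10-KO cells. Per the labels' protocols, 50 ng of DNA was digested with MspI for 3 hours, ligated to methylated adaptors, bisulfite converted, amplified by PCR and size selected to 150 to 500 bp. Groups and replicate numbers were taken from the sample titles and the genotype labels.

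The authors deposited 1 table per library with, for each cytosine of a CpG site, its position, its methylation as a percent, and the counts of calls that read it as methylated and as unmethylated. The deposited percent differs from the methylated count over both counts by less than 0.0001 points in every row, and the deposited counts are whole numbers and not normalised; they were used for all tests. Whether calls were filtered before the authors counted them is not stated. Trim Galore and Bismark 0.10.1 with the mouse build mm9 are named in the submitters' processing notes, with no role or order. The settings for trimming, filtering and removal of PCR duplicates are not given in the sources used here. Reads were not counted by molecule, so duplicate reads can make counts look more precise than they are, and the counting errors given cover counting only. Cytosines of MspI sites can also carry bases filled in during library preparation, which is removed only by some trimming settings.

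From the deposited tables, cytosines of chromosomes 1 to 19, X and Y covered at least 10 times in every library were kept; mitochondrial calls were looked at apart. A library's level is the mean over these 1899909 cytosines, each weighing the same. Windows of 1 kb that do not overlap were kept if they held at least 3 such cytosines, and their level is the methylated count over all counts in the window. Coordinates are 1-based in mm9. The gene table used here names another assembly (GRCm38.p6), so no gene was assigned to a position. The planned tests of gene promoters and of gene lists (imprinted, germline, pluripotency, fibroblast and other lists) needed an annotation of mm9 and were not run.

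Cytosines and windows were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on methylated and unmethylated counts, with a term per library, methylated state, and genotype by methylated state, and adjusted by the Benjamini-Hochberg method. A call needed an adjusted p below 0.05 and a difference of group mean levels of at least 10 percentage points. Features with no methylated or no unmethylated call in any library got a p of 1 and stayed in the adjustment. Of the windows 121180 of 121563 and of the cytosines 1187050 of 1899909 could be fitted. Means per library were compared with a two-sided exact permutation test (scipy 1.17.1), whose smallest p is 0.333 with 2 against 2 libraries. The text names the 10 windows with the largest fall and the 10 with the largest rise among those called and with both KO libraries on the same side of both WT libraries, where windows less than 2 kb apart count as 1; only 3 had a rise.

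The test was tried on simulated data made from the measured depths, with the spread between libraries set to that of the WT pair at each methylation level. For 1 kb windows (121563 simulated) it called 40 of 100 windows changed by 15 points and 94 of 100 changed by 30 points, 1 unchanged window was called, and 4.69% of unchanged windows had an unadjusted p below 0.05. For single cytosines (100000 simulated) it called 0 of 100 changed by 15 points and 7 of 100 changed by 30 points, with 0 unchanged cytosines called. Simulations tried before this one had 1 spread for all levels. With an intra-class correlation of 0.01, which was used first, the test called 0 of 100 windows changed by 30 points; it called 65 with 0.003 and 92 with 0.001. On these data 3 quasi-Poisson forms of the edgeR test called 81, 80 and 0 of 100 with 0.01, and limma called 0 with any of the 3 spreads. The simulated spread was then set to that of the WT pair, and the test was left as it was. The test at single cytosines therefore has little power for rare changes, and the recovery holds only for the spread of the WT pair, which is below that of the KO pair.

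The alternatives were other coverage minimums (5 and 20), limma 3.58.1 on logit methylation with 0.5 added to each count, Fisher's exact test on pooled counts, no minimum difference or 25 points, centring on the library-wide shift over features between 10 and 90%, sites above the 99.9th percentile of coverage left out, autosomes only, windows of 500 bp and 2 kb, at least 10 cytosines per window, each library left out in turn, and the replicate number as a block. These were chosen before the data were examined. Leaving out chromosome 8, choosing intermediate windows on WT replicate 1, and all the alternatives of the scan of chromosome X were chosen after seeing the data.

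Depth per chromosome was taken from the share of autosomal calls, without positions above the 99.9th percentile of depth in any library. With 26 to 30 calls at the median cytosine, the level of a single cytosine in 1 library is coarse, which windows and library means average out.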

Results

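Reduced representation bisulfite sequencing, which reads CpG methylation in the CpG-rich part of the genome after DNA is cut with the enzyme MspI, was carried out on mouse embryonic stem (ES) cells of 2 genotypes. Naa10 is the X-linked gene for the catalytic subunit of a major N-terminal acetyltransferase, and the comparison asks whether CpG methylation, that of imprinted regions included, differs in cells without it. There were 2 libraries from wild-type (WT) ES cells and 2 from Naa10 knockout (KO) ES cells. The cells were grown in N2B27 medium with LIF and inhibitors of Mek and Gsk3 on irradiated fibroblast feeders, and then for 5 passages without feeders before DNA was taken. WT replicate 1 held 79540412 methylation calls and WT replicate 2 held 68586396. KO replicate 1 held 68929594 and KO replicate 2 held 70594987. Each library covered 3795379 to 3918007 cytosines of CpG sites, with the cytosines of the 2 strands listed apart. A set of 1899909 cytosines was covered at least 10 times in all 4 libraries, at a median depth of 26 to 30 calls, and these carry the comparisons below. Whether the libraries of a genotype came from separate cultures or clones is not stated, so the p-values measure only the spread between these libraries, which may be technical. The 2 WT libraries differed in methylation by little more than counting error, with a chi-square per degree of freedom of 1.08 over 304767 cytosines. For the 2 KO libraries this value was 2.35.

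Chromosome X, which carries the targeted gene, was looked at first. Bisulfite data show no expression, and the position of Naa10 in the mouse build mm9 was not checked here. The whole of chromosome X was therefore scanned for cytosines covered at least 10 times in both WT libraries and not at all in either KO library. Such a scan cannot say whether Naa10 itself is changed, and so does not check the genotype labels. There were 46 such cytosines in 12 clusters, all between positions 69515475 and 83829617 of chromosome X (mm9). The longest cluster held 16 cytosines between 71166662 and 71166934, where the WT libraries had 17 to 34 calls per cytosine and the KO libraries had 0 at these 16 cytosines. Over all 19 cytosines listed within these bounds the KO libraries together had 3 calls. The nearest cytosines with calls in both KO libraries lay at 71160779 on one side and 71167646 on the other. In the opposite direction, 3 cytosines of chromosome X were covered in both KO libraries and in neither WT library, 2 of them inside the same interval. On the autosomes, 49 cytosines in 10 clusters were covered in both WT libraries and in neither KO library, and 4 cytosines in the opposite direction. The mixed arrangements, each setting 1 WT and 1 KO library against the others, gave 0 such cytosines. The WT and KO libraries thus differed in sequence coverage at fixed places, and the libraries of a genotype shared the difference. The number depends on the depth asked for, with 96 cytosines of X at a minimum of 5 calls and 9 at 20, and it rose to 139 when KO replicate 1 was left out.

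**Figure D1:**
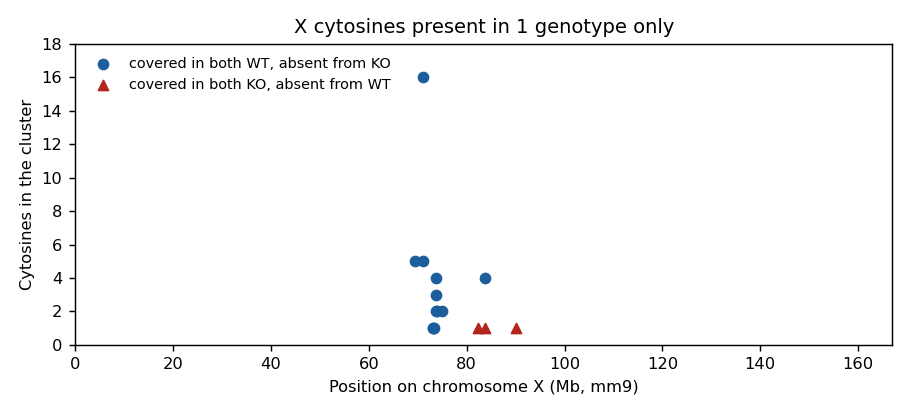
Clusters of cytosines on chromosome X that were covered at least 10 times in both libraries of 1 genotype and absent from both libraries of the other. The horizontal axis is the position in Mb (mm9) and the vertical axis the number of cytosines in the cluster; the 12 clusters absent from the KO libraries all lie between positions 69515475 and 83829617.

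CpG methylation was far lower in the KO libraries than in the WT libraries. Over the 1899909 shared cytosines the mean level was 30.5% ± 0.00337 (SD, n = 2) in WT and 8.81% ± 2.45 (SD, n = 2) in KO, a KO minus WT difference of -21.7 percentage points. KO replicate 1 had a mean level of 10.5% and KO replicate 2 of 7.08%, so both lay below both WT libraries. The share of cytosines with a level of 80% or more was 24.3% in each WT library, 0.347% in KO replicate 1 and 0.0714% in KO replicate 2. Cytosines with no methylated call made up 48.1% and 49.2% of the set in the WT libraries, and 56.3% and 59.4% in the KO libraries. The two-sided exact permutation test of the 4 library means gave p = 0.333, the smallest value that 2 against 2 libraries allow, so this test cannot reach 0.05 whatever the difference. When 1 kb windows weighed the same instead of cytosines, which gives CpG-poor sequence more weight, the means were 59.2% in WT and 17.0% in KO, a difference of -42.3 points.

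Methylation was lower in KO in most of the measured windows. Words such as lost, fell, rose, kept and remained describe KO levels relative to WT here and below. With no earlier sample of the cells, these libraries cannot tell a fall in KO from a rise in WT. Of 121563 windows of 1 kb with at least 3 shared cytosines, 92796 had a lower level in KO by at least 10 percentage points at an adjusted p below 0.05 in edgeR's quasi-likelihood test on methylated and unmethylated counts, with Benjamini-Hochberg adjustment, and 3 had a higher level. In the windows called lower the median level was 85.5% in WT and 20.7% in KO, and 64660 of them lost 50 points or more. Among the 90648 windows with a mean WT level of 20% or more, 90345 (99.7%) were called lower. Against a library-wide shift, taken out by centring each library on its median logit level (limma), 6258 windows were called below the shift and 8887 above it, windows that rose included. Centring itself places windows on both sides, so these counts say nothing about the direction of the calls made on the levels as measured.

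The 10 windows with the largest falls among those with both KO libraries below both WT libraries lay on chromosomes 3, 4, 6, 13, 14 and 19, and their levels fell by 90.7 to 93.8 points. On chromosome 4, the window 65877001 to 65878000 had a level of 98.8% ± 1.68 (SD, n = 2) in WT and 5.01% ± 2.67 (SD, n = 2) in KO, with an adjusted p of 3.33e-25 in the edgeR test. On chromosome 19, the window 49194001 to 49195000 went from 98.2% to 4.72%, and the window 31583001 to 31584000 from 97.3% to 5.67%. On chromosome 14, the window 53194001 to 53195000 went from 93.0% to 1.37%, and on chromosome 13 the window 73703001 to 73704000 went from 93.5% to 1.70%. On chromosome 6 the windows starting at 121619001, 49446001 and 59918001 ended at KO levels of 5.68%, 2.78% and 1.80%. The window starting at 112963001 of chromosome 3 ended at 3.75%, and that starting at 138617001 of chromosome 4 ended at 5.51%. These windows are small, with 3 to 6 cytosines and 33 to 108 calls per library.

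A rise was called in 3 windows. On chromosome 18, the window 38759001 to 38760000 rose from 2.81% ± 1.54 (SD, n = 2) in WT to 22.2% ± 9.25 (SD, n = 2) in KO, with an adjusted p of 4.16e-06 in the edgeR test. The window 44814001 to 44815000 of chromosome 19 rose from 5.77% to 19.2%, and the window 151649001 to 151650000 of chromosome 4 rose from 6.46% to 17.7%. With no minimum difference 163 windows were higher in KO, and these started from almost no methylation, with a median level of 0.0959% in WT and 0.578% in KO. In 150 of the 163 both KO libraries lay above both WT libraries. The windows were chosen on their difference in these same libraries, so this is no separate support for a rise. The adjustment ran over all windows, most of them called lower, so it does not limit the share of false calls among the rises. The chromosome 4 window had an unadjusted p of 0.0181 and an adjusted p of 0.0219 in the edgeR test. The number of windows called higher was 1 without WT replicate 1, 1 without WT replicate 2, and 13 without KO replicate 2.

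At single cytosines the picture was the same in direction. Of the 1899909 shared cytosines, 654306 were called lower in KO and 26 higher by the same test and thresholds, and 712859 had no methylated call in any library or no unmethylated one and could not differ. At the median, the cytosines called lower fell by 60.8 points. The number called higher was 2 without WT replicate 1, 1 without WT replicate 2, 44 without KO replicate 1 and 173 without KO replicate 2. Relative to the library-wide shift, 70563 cytosines were called below the shift and 74122 above it.

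Lower KO levels were found in every class of CpG density. Windows were split by the number of shared cytosines they hold. In the 77330 windows with 3 to 9 cytosines the mean level was 73.0% ± 0.00627 (SD, n = 2) in WT and 20.8% ± 5.80 (SD, n = 2) in KO. In the 23073 windows with 10 to 19 cytosines it was 57.0% in WT and 16.5% in KO, and in the 9750 windows with 20 to 39 cytosines 21.7% in WT and 6.11% in KO. CpG-dense windows were almost unmethylated in both genotypes: the 7379 windows with 40 to 79 cytosines had 3.12% in WT and 1.05% in KO, and the 4031 windows with 80 or more had 0.820% in WT and 0.367% in KO. KO levels as a percentage of WT levels were 28.5%, 28.9% and 28.2% in the 3 sparser classes, 33.5% with 40 to 79 cytosines and 44.7% with 80 or more. The last 2 shares rest on low levels, where false methylated calls in all libraries would raise the share. The rate of such calls was not measured. Both KO libraries lay below both WT libraries in each class, and the two-sided exact permutation test gave p = 0.333 in each class, 0.333 after Benjamini-Hochberg adjustment over the classes, which is the smallest p it allows. At a coverage minimum of 20 calls the difference in the class with 20 to 39 cytosines was -6.91 points in place of -15.6, and in the class with 40 to 79 cytosines -1.08 in place of -2.08. At a minimum of 5 these differences were -21.5 and -3.22. The classes were formed anew at each minimum from the cytosines that passed it. They therefore depend on coverage as well as sequence and hold different windows at each minimum.

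**Figure D2:**
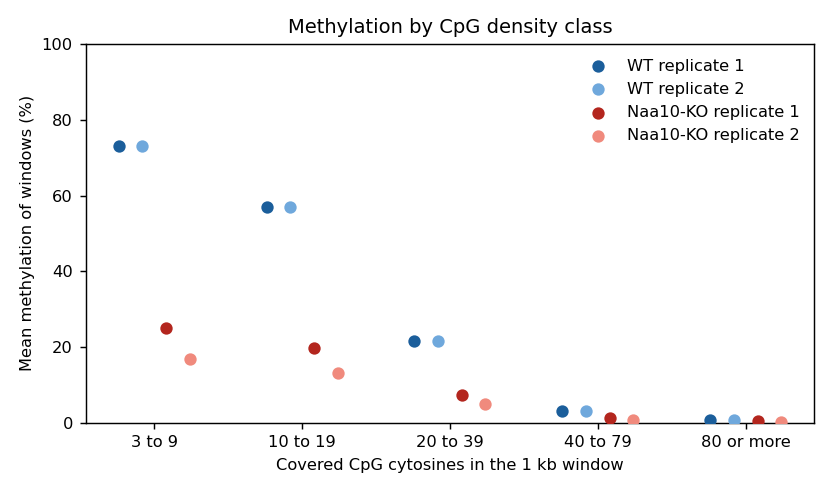
Mean methylation level in percent of 1 kb windows (vertical axis) by the number of covered CpG cytosines in the window (horizontal axis), with 1 point per library. The WT libraries overlap at 73.0% in the sparsest class while the KO libraries are at 24.9% and 16.7%, and all 4 libraries are below 1% in the densest class.

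How much methylation remained depended on the level in WT cells. Windows were binned by their level in WT replicate 1, and the levels were then read in the other 3 libraries, so that the binning does not shape the WT value. Windows binned at 50 to 60% averaged 55.9% in WT replicate 2, 14.4% in KO replicate 1 and 9.75% in KO replicate 2. Windows binned at 90 to 100% averaged 92.4%, 36.8% and 25.02%. The mean KO level was thus 21.6% of the WT level in the bin at 50 to 60%, the lowest share of all bins, and 33.5% in that at 90 to 100%. The share did not rise steadily with the WT level. It was 36.7% below 10%, 25.6% at 10 to 20% and 21.6% to 23.2% in the bins from 20 to 70%. At 70 to 80% it was 24.6% and at 80 to 90% 26.8%. KO replicate 2 held 65.4% to 71.6% of the level of KO replicate 1 in every bin from 20% up.

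**Figure D3:**
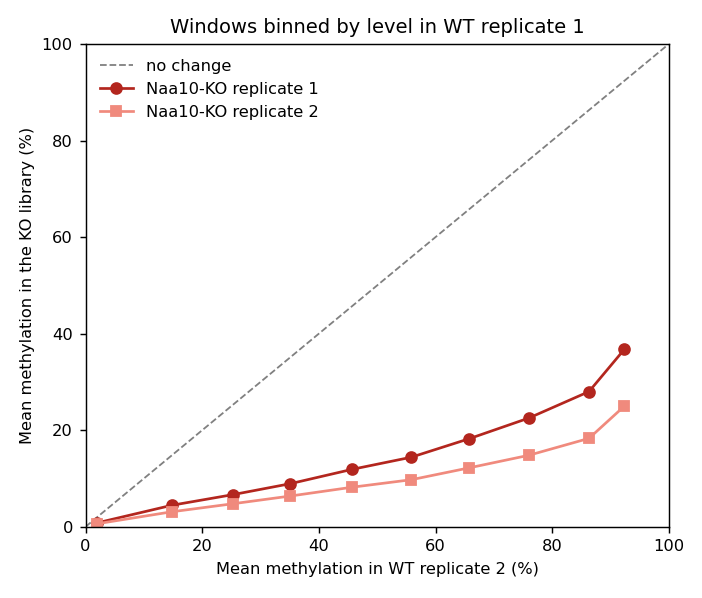
Mean level in percent of each KO library (vertical axis) against WT replicate 2 (horizontal axis), for 1 kb windows in 10 bins of the level in WT replicate 1. Both KO lines run far below the dashed line of no change and steepen at the top, where KO replicate 1 reaches 36.8% and KO replicate 2 reaches 25.02%.

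A small set of windows kept a high level in KO. Both KO libraries had a level of 50% or more in 982 of the 121563 windows, and 977 of these were among the 57133 windows with a WT level of 80% or more. None of the 982 had a higher mean level in KO than in WT. The following 3 windows were chosen after their values were seen. On chromosome 6, the window 67544001 to 67545000 had a level of 98.3% ± 0.663 (SD, n = 2) in WT and 90.04% ± 1.46 (SD, n = 2) in KO, from 84 to 112 calls per library; it did not pass the minimum difference. The window 111382001 to 111383000 of chromosome 3 went from 97.8% to 82.1%. Among windows with 20 or more cytosines, the window 5663001 to 5664000 of chromosome 15 kept the highest mean level in KO, at 69.1% ± 12.5 (SD, n = 2) against 97.5% in WT.

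Windows of intermediate level were examined because imprinted regions, methylated on 1 parental copy, have levels near the middle of the range. The rule fixed before the data were examined took windows with at least 20 cytosines and a mean of 35 to 65% over all 4 libraries. It selected 1806 windows, which had 80.1% ± 0.123 (SD, n = 2) in WT and 21.3% ± 6.50 (SD, n = 2) in KO, so these were mostly highly methylated windows that lost methylation. None of the windows lay between 35 and 65% in each of the 4 libraries. A second choice, made after seeing the data, took windows with at least 20 cytosines and 35 to 65% in WT replicate 1. These 872 windows averaged 49.3% in WT replicate 2, 14.1% in KO replicate 1 and 9.32% in KO replicate 2, and both KO libraries were below both WT libraries in 872 of 872. None had 30% or more in both KO libraries. The highest level of any of them was 39.6% in KO replicate 1 and 25.9% in KO replicate 2. The two-sided exact permutation test of the library means gave p = 0.333 for either choice, the smallest it allows. Which of the windows are imprinted regions was not determined here.

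Every autosome and the X and Y chromosomes had lower methylation in KO. Autosomal means ran from 26.9% (chromosome 19) to 32.6% (chromosome 8) in WT and from 7.71% (chromosome 11) to 9.53% (chromosome 13) in KO, and the KO level was 28.0% to 30.5% of the WT level. Chromosome X had 38.5% ± 0.0690 (SD, n = 2) in WT and 11.6% ± 3.32 (SD, n = 2) in KO over 25758 cytosines, 30.1% of the WT level. Chromosome Y had 71.2% in WT and 13.7% in KO over only 38 cytosines. The two-sided exact permutation test gave p = 0.333 for each chromosome, the smallest it allows. X took 1.33% of calls in WT and 1.31% in KO, and Y took 0.00856%, 0.00837%, 0.0139% and 0.00732% of calls in WT replicates 1 and 2 and KO replicates 1 and 2.

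Chromosome 8 differed in depth between the genotypes. Its share of the autosomal calls was 7.10% ± 0.0127 (SD, n = 2) in WT and 6.11% ± 0.00522 (SD, n = 2) in KO, a KO to WT ratio of 0.861. For chromosome 14 the ratio was 0.956, and for the remaining autosomes it was 0.996 to 1.03. Without chromosome 8 the number of windows called lower was 86864 of 114063.

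**Figure D4:**
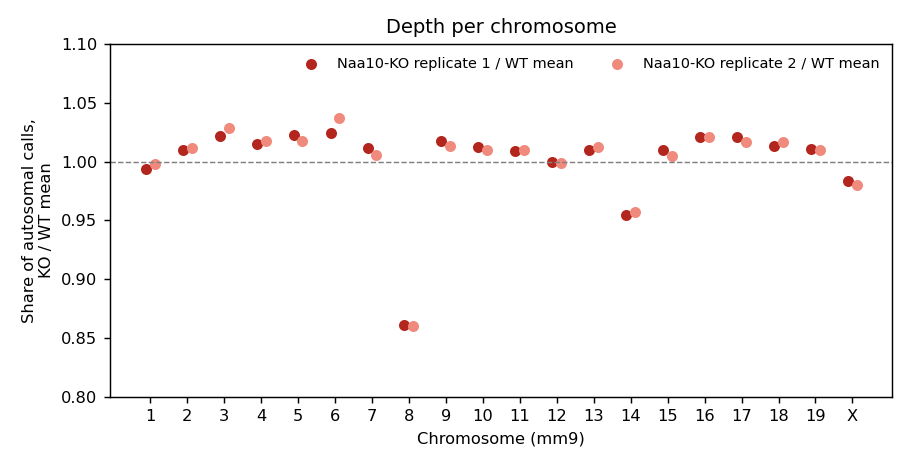
Share of autosomal calls on each chromosome in each KO library, divided by the mean share of the 2 WT libraries (vertical axis, starting at 0.80), by chromosome (horizontal axis, mm9). Chromosome 8 stands at 0.861 and 0.860 in the KO libraries and chromosome 14 at 0.955 and 0.957.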

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

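The tests of explanations below were all chosen after the results they concern had been seen.

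The main pattern is the low CpG methylation of the KO libraries. Less complete bisulfite conversion of the WT libraries would add false methylated calls everywhere. In windows with 80 or more cytosines the KO minus WT difference was only -0.453 points, against -42.3 points over all 1 kb windows, each weighing the same. The mitochondrial level was 2.04% and 1.38% in WT and 0.612% and 0.830% in KO, a difference of -0.986 points. A small difference in conversion therefore stays open, and it could account for the 0.453 points in the densest windows. A second X chromosome in the KO cells, which is known to lower methylation in mouse ES cells, would raise the depth of X, and the X share of autosomal calls in KO was 0.982 of that in WT. The loss of Naa10 and the history or culture of the cell lines apart from the knockout cannot be told apart, because each genotype may be 1 line; the lines differ elsewhere too, as in the share of all calls on chromosome 8 (KO to WT ratio 0.857). The effect of the genotype stays an untested hypothesis.

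Depth on chromosome 8 was set apart because it lies outside the methylation comparison and differs between the genotypes, with a KO to WT ratio of 0.861 after the deepest positions were left out, so a few positions of very high depth do not account for it. Recovery of CpG-rich or CpG-poor fragments is argued against by ratios of 0.855 to 0.867 in 3 classes of CpG density. In 14 of 14 bins of 10 Mb along the chromosome the ratio was below 0.9, against 0 of 231 bins on the other autosomes apart from chromosome 14, which is what a difference in copy number between the cells would give. Relative to the other autosomes, chromosome 8 stood at 1.19 in both WT libraries and at 1.00 in both KO libraries, so a candidate explanation is a gain of chromosome 8 in part of the WT cells. Chromosome 14 stood at 1.05 in both WT libraries, where the highest of the other autosomes was at 1.03, and at 0.991 and 0.994 in the KO libraries. Its lowest bin had a KO to WT ratio of 0.897, and the cause was not tested.

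The 46 cytosines of chromosome X covered in WT and absent from KO were set apart because absent coverage is outside the methylation comparison. One large deletion across the interval from 69515475 to 83829617 is argued against by 2657 cytosines in it that both KO libraries covered at least 10 times. Chance loss at low depth is argued against by the 4 mixed arrangements of the libraries, the highest of which gave 0 such cytosines on X. Sequence differences gathered in 1 interval, for example a different haplotype, stay open. The clusters lie closer together than 10000 random draws of 12 windows from X (permutation p = 0.0001), but this closeness is what prompted the explanation, so it is no test of it. A small deletion at the longest cluster stays open as well; the KO libraries together had 3 calls within its bounds.

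The mitochondrial share of calls was 0.160% ± 0.0690 (SD, n = 2) in KO and 0.0556% ± 0.000227 (SD, n = 2) in WT, a signal outside the methylation comparison; its level was 0.721% in KO and 1.71% in WT.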

How the results depend on the processing

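Leaving out chromosome 8, the choice of intermediate windows on WT replicate 1 and the settings of the X scan were chosen after seeing the data. The 10 mean differences between KO and WT kept their sign in all 79 alternatives. In each of the 10 both KO libraries lay below both WT libraries. Leaving out a library, or the replicate block, therefore could not change the sign, and those alternatives are no test of it. The difference over all cytosines ran from -42.3 (1 kb windows weigh the same) to -19.8 points (reads weigh the same). The windows called numbered 92799 (76.3% of all windows kept), and 52559 (68.2%) at a coverage minimum of 20 and 21337 (48.2%) with at least 10 cytosines, where fewer windows were kept and a smaller share of them was called. Relative to the genome-wide shift 15145 were called, 8887 of them above the shift, the 3 windows called higher included; the centring places windows on both sides by construction. The cytosines called numbered 654332 (34.4% of all cytosines kept), and 359188 (33.95%) at a coverage minimum of 20, with fewer kept, and 144685 relative to the shift, 74122 of them above it.

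Counts of rises are small and depend on the settings, and the adjustment over all features does not limit false calls among them. From 3 windows they went to 163 with no minimum difference, 6 at a coverage minimum of 5, 1 at 20, 1 with windows of 2 kb, 0 with a minimum difference of 25 points or at least 10 cytosines, and 1 to 13 with a library left out. From 26 cytosines they went to 3 with a minimum difference of 25 points, 156 with limma, 123 with Fisher's exact test, which leaves out the spread between libraries, and 1 to 173 with a library left out. Except where the construction says it, the cause was not tested. The X cytosines absent from KO went from 46 to 96 at a minimum depth of 5 and 9 at 20, and to 59 to 139 with a library left out.

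Of the 3 windows called higher, that on chromosome 18 lost its call at 25 points. Those on chromosomes 19 and 4 lost it there too and without either WT replicate, that on chromosome 19 also at a coverage minimum of 5 (7.34 points) and that on chromosome 4 also without KO replicate 1 (8.84 points). The 3 windows named for the level they kept lost less than the shift, by 22.9 (chromosome 6), 18.0 (chromosome 3) and 5.91 points (chromosome 15). They were chosen for a high level in KO, which favours this outcome, so it is no test of them. With the replicate number as a block 92739 windows and 644906 cytosines were called. Same-numbered libraries did not deviate together (correlation over windows -0.000609), the labels state no pairing, and for means the block changes nothing by construction. The alternatives for promoters and gene lists were not run, for want of an annotation of mm9.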

Other observations

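The tests in this part were all chosen after the values had been seen.

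CpG-dense windows that are methylated in WT cells lost methylation too. The 1188 windows with at least 20 cytosines and 80% or more in WT replicate 1 averaged 88.5% in WT replicate 2, 32.2% in KO replicate 1 and 21.0% in KO replicate 2. Both KO libraries fell below 20% in 121 of them and stayed at 50% or more in 13. The 37 such windows with at least 40 cytosines had 88.9%, 32.4% and 20.3%. Of the 163 windows that were higher with no minimum difference, 3 lay between 36819001 and 36828000 of chromosome 13, with medians of 0.533% in WT and 2.65% in KO, and 2 adjoining windows lay between 126777001 and 126779000 of chromosome 10, with 1.24% and 5.22%; whether they lie together more than chance gives was not tested.

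Loss by the same factor at every WT level was tested as a hypothesis and is argued against. From the bins of 20% upward, the share of the WT level kept in KO differed 1.55 times between the highest and the lowest bin, and by 1.57 times in KO replicate 1 and 1.55 times in KO replicate 2 taken alone. Of these bins, that at 90 to 100% kept the most, 33.5%, but the bin below 10% kept 36.7%. The latter rests on KO levels of 0.790% and 0.612% against 1.91% in WT replicate 2, where false methylated calls would raise the share.

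Which windows kept more methylation was shared by the KO libraries. Among 24693 windows with 90% or more in both WT libraries, the levels of the KO libraries correlated across windows, which are not independent replicates, with r = 0.804, against -0.0185 to 0.0206 in 1000 shuffles. Counting error alone would give a correlation near that of the shuffles. Of the 2471 windows in the top 10% of KO replicate 1, 1519 were in the top 10% of KO replicate 2, where independent lists would share 248. A hypothesis is that local sequence or chromatin may set how much methylation a region retains. The correlation and the overlap were not adjusted for WT level within this range or for CpG density, so they do not test it. If both libraries come from 1 line, a shared history of that line would also give such values.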
